A study of Homo sapiens with 2 samples.

How the data were processed

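RNA immunoprecipitation sequencing (RIP-seq) was done on HK2 cells, a human renal tubular epithelial line, transfected with a plasmid for Flag-tagged YTHDF1. The 2 libraries were 1 input library and 1 library of RNA recovered with an antibody to the Flag tag (the IP). Per the labels' protocols, purified RNA was fragmented, copied with random primers into double-stranded cDNA, ligated to adapters and amplified by PCR. The protocol names no strand-marking step, and no molecular identifiers are mentioned. How ribosomal RNA or polyadenylated RNA was handled is not given in the sources used here.

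Per the submitters' processing notes, the tools were cutadapt 1.9, FastQC, HISAT2, StringTie 1.3.4d, DESeq2 and edgeR, and the genome build was hg38. The role of each tool, the annotation and the treatment of reads that match several places are not given in the sources used here. The authors' deposited table gave RPKM (reads per kilobase of exon, scaled to library size) for each gene in each library, with a gene length, and no raw counts. The authors also deposited a log2 fold change and a p-value for each gene, and a list of genes called bound. No replicate stood behind either of these deposited columns, since each arm had 1 library. The deposited bound list, of 4087 genes, was exactly the set with a deposited log2 fold change of at least 1 and a p-value under 0.05. The 17326 genes of the table all had more than 1 CPM in at least 1 library.

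Whole reads were recovered from RPKM and gene length. Every value came out as a whole number of reads within 0.01 reads, which gave totals of 15332318 reads for the IP and 15637003 for the input. These totals are the library sizes that the scaling implies, and what they count is not given. The genes of the table held 15299816 IP reads and 15599510 input reads, and some reads were counted for more than 1 overlapping gene. RN7SK and the overlapping AL162581.1 had the same 31921 IP reads and 202067 input reads, and genes of the PCDHG cluster, which share their last exons, also had equal counts. Genes were matched to GENCODE release 29, the reference at hand for hg38. Of the 17326 genes, 16851 matched, 16458 of them by symbol and the others through the gene ID of a newer symbol. The deposited lengths equalled the union of the exon intervals given in the same deposited table, with 0 mismatches. They were not compared with the exons of GENCODE release 29, whose gene start and end were the same at 8994 genes. In the table, 1920 genes shared over 50% of their exon bases with another listed gene, and without strand their reads cannot be separated.

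The main value was log2((IP RPKM + 1)/(input RPKM + 1)), so folds of low genes are understated. With 1 library per arm no spread could be estimated, and no p-value was used to call genes. P-values were computed only at assumed dispersions, for comparison with the deposited ones. Genes with a mean RPKM of at least 1 were called higher in the IP at a log2 ratio of at least 1, and lower at -1 or below. Ratios of depth-scaled reads carry exact (Clopper-Pearson) 95% intervals, which cover counting error only and neither PCR duplication nor variation between cultures. For a library at 0 reads the floor was 3 counts. A gene list was described by the percentile of its median log2 ratio among 10000 random lists of the same size, drawn from 20 bins of mean expression. A list with at least 5 measured members was called above at a percentile of 97.5 or more and below at 2.5 or less. These percentiles describe the 2 libraries and do not test the conditions. Of 31 lists tested, 0.775 would fall on each side by chance if their members were random genes of like expression. Members of a list can share length, GC content and other properties that go with the ratio. The number of lists past the limits therefore cannot be judged against 0.775 alone.

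All 32 lists, the size rule and the rule for named genes were fixed before the data were examined. The rule named YTHDF1, YTHDF2 and YTHDF3, the 15 highest and 10 lowest protein-coding genes with a mean RPKM of at least 5, the 5 highest non-coding genes at that floor, and the 2 highest and 2 lowest members of each list. XIST and Y-linked genes were left out. Not every gene the rule names is reported here. Alternatives covered the pseudocount, the filter on low values, the scaling between libraries, the gene set, the size rule, length-matched random lists and whole reads as CPM. A pair of further alternatives, a rescaling without mitochondrial and small non-coding RNA and a limit of 10% shared exon bases, was chosen after seeing the data.

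The procedure was tested on simulated data for the IP against input comparison, with 14227 genes and a simulated dispersion of 0.01. The size rule recovered 50 of 50 genes changed 4-fold, 15 of 50 changed 2-fold, 0 of 50 changed 1.5-fold and 10 of 50 changed 0.5-fold. It passed 15 of 14027 unchanged genes. Changed lists were found in 5 of 5 cases at each fold, and 6 of 100 unchanged lists fell outside the percentile limits. In the simulation unchanged genes had a true ratio of 1, and all members of a changed list shared the same fold. The real ratios spread more widely and follow gene properties, so these rates need not hold for the 2 libraries. The intervals covered the simulated ratio for 95.6% of genes in a separate draw with counting error only, without the dispersion or changed genes. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.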

Results

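YTHDF1 is a cytoplasmic protein that binds N6-methyladenosine (m6A), the commonest internal modification of mRNA. The series asked which transcripts bind YTHDF1 in HK2 cells, an immortalised line from human proximal tubule. RNA recovered with the Flag antibody was compared with input RNA of cells carrying the same Flag-YTHDF1 plasmid. Each was 1 library, with a recovered size of 15332318 reads for the IP and 15637003 for the input. Neither arm had a replicate, and no control precipitation from untagged cells or with another antibody was analysed here, so the differences below have no replicate check. In what follows, "higher" and "lower" refer to the IP relative to the input and, for counts of genes, to a log2 ratio of at least 1 in size.

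On the deposited RPKM scale, the IP held more mRNA of zinc finger, chromatin, immediate early and developmental signalling genes, and less mitochondrial, ribosomal protein, histone and small structural RNA. Among 14227 genes with a mean RPKM of at least 1, 2220 were higher, 872 were lower and 11135 lay between. Protein-coding genes made up 1736 of the higher and 586 of the lower genes. The counting interval of the read ratio lay above 1 for 2216 of the higher genes and below 1 for 868 of the lower genes. The size rule and the expression floor, applied to the same reads, largely fix this outcome, so it is no separate evidence. The median log2 ratio of all these genes was 0.22 (quartiles -0.32 and 0.75), and higher genes were 71.8% of those past the size rule. Centring the ratios on that median gave 1290 higher and 1473 lower genes (46.7% higher), whereas giving both libraries the same RPKM sum gave 8311 and 75 (99.1% higher), so the split depends on the scaling.

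**Figure D1:**
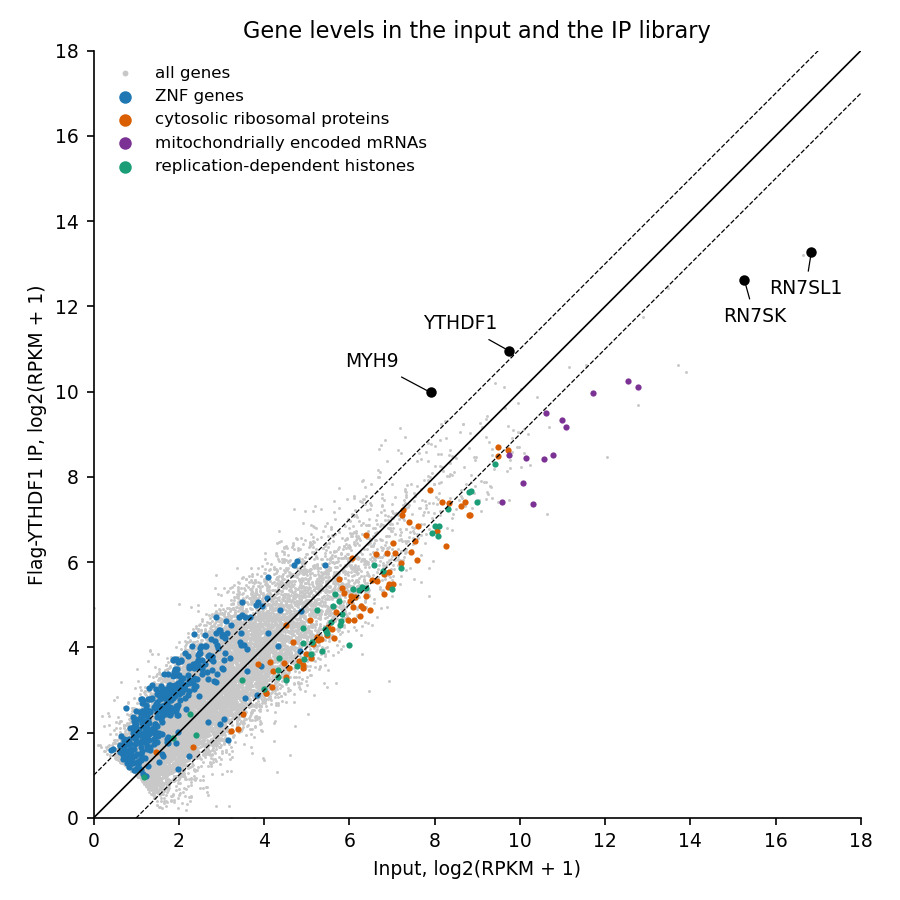
Each point is a gene with a mean RPKM of at least 1, placed by log2(RPKM + 1) in the input (horizontal) and in the Flag-YTHDF1 IP (vertical), with 1 library on each axis. The solid line marks equal levels and the dashed lines a log2 difference of 1 on the deposited scale. ZNF genes sit mostly above the solid line (median log2 ratio 0.97), ribosomal protein mRNAs (-1.09), histone mRNAs (-1.02) and mitochondrial mRNAs (-2.13) below it, and on a scale of equal RPKM sums the ribosomal median is -0.03 and the histone median turns to 0.05. RN7SL1, RN7SK, YTHDF1 and MYH9 are marked.

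YTHDF1 mRNA, transcribed from chromosome 20 (hg38, 63195429 to 63216139, minus strand) and from the plasmid, was abundant in both libraries, at 1994 RPKM in the IP and 854 in the input. Its log2 ratio was 1.22, from 98003 IP reads and 42828 input reads, a read ratio of 2.33 (95% interval 2.31 to 2.36). The table does not separate plasmid from endogenous reads. Of its paralogs, YTHDF3 reached 25.2 RPKM in the IP and 8.41 in the input, a log2 ratio of 1.48 (read ratio interval 2.77 to 3.25). YTHDF2 was at 26.7 and 14.99 RPKM, a read ratio of 1.78 (1.64 to 1.94) and short of the size rule. Since the input also came from transfected cells, its YTHDF1 level cannot be set against an untransfected level here.

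By the main log2 ratio, the highest protein-coding gene was ZBED1, a BED-type zinc finger protein (log2 ratio 2.54). It was at 40.9 RPKM in the IP and 6.23 in the input (read ratio 6.57, interval 5.96 to 7.27). HPS6, a gene of lysosome-related organelle biogenesis with a single exon on chromosome 10 (102065349 to 102068036, plus strand), followed at 57.1 and 9.35 RPKM (log2 ratio 2.49). The other genes of the highest 15 were ANKRD33B (2.41), FJX1 (2.35), RAB40C (2.34), THEMIS2 (2.32), FAM20C (2.26), MYH10 (2.25), SEPHS2 (2.20), SPEN (2.19), POGK (2.19), RTL6 (2.17), ARHGAP35 (2.17), IRS1 (2.16) and CHPF2 (2.16). Among them were MYH10, a non-muscle myosin heavy chain, at 147 and 30.1 RPKM, SPEN, a transcriptional corepressor, at 73.2 and 15.2 RPKM, and IRS1, the insulin receptor substrate, at 45.6 and 9.41 RPKM. All 15 genes keep a log2 ratio above 1 when the ratios are centred on the median, which lowers each by 0.22.

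The 10 lowest protein-coding genes were 7 mitochondrially encoded mRNAs and 3 nuclear genes. MT-ND1, a complex I subunit, was at 163 RPKM in the IP and 1260 in the input (log2 ratio -2.95, read ratio 0.129, interval 0.124 to 0.135). MT-CO1, the catalytic subunit of cytochrome c oxidase, was at 1102 and 6976 RPKM (-2.66). MT-ND6 (-2.30), MT-ATP6 (-2.27), MT-ND2 (-2.20), MT-CO2 (-2.19) and MT-CO3 (-2.13) were the other mitochondrial members. The nuclear genes were S100A11, a calcium-binding protein, with 454 IP and 2084 input reads (-2.15), HSPE1, the mitochondrial co-chaperonin, with 280 and 1255 reads (-2.03), and BEX2 with 38 and 212 reads (-2.02, read ratio interval 0.126 to 0.259).

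Of the 31 lists tested, 5 lay above random lists of like expression. ZNF genes, most of which encode zinc finger transcription regulators, had the largest numbers, with 177 of 376 measured members higher, 1 lower, a median log2 ratio of 0.97 and a percentile of 100. ZNF304 (1.96) and ZNF12 (1.84) were highest, and ZNF326 (-1.32) was the lower gene. Reads shared among ZNF paralogs cannot be separated in the table. Chromatin regulators had 22 of 61 members higher and 1 lower (median 0.89, percentile 100), among them ARID1A, a SWI/SNF subunit, at 1.95 and the acetyltransferase KAT6A at 1.74. EZH2, the Polycomb methyltransferase, was the lower gene (-1.05). Immediate early transcription factors and feedback regulators had 12 of 28 higher and 0 lower (median 0.90, percentile 100), with IER5 (1.84) and SPRY2 (1.58) highest and ID2 (-0.33) and FOSL1 (-0.16) lowest.

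Wnt, Notch and Hippo pathway genes had 16 of 38 members higher and 0 lower (median 0.79, percentile 99.98), led by the Wnt receptor FZD7 (2.15) and the atypical cadherin FAT1 (2.01), whereas TCF7L2 was at -0.62. Matrix and TGF-beta genes had 7 of 37 higher and 0 lower (median 0.71, percentile 99.96). Their highest members were the SMAD corepressor SKI (1.84) and SMAD3 (1.79), and the lowest were the integrin ITGB1 (-0.85) and SPARC (-0.38). The medians of these 5 lists stayed positive under median centring, the trimmed mean and equal RPKM sums. Matching the random lists on coding transcript length as well put the matrix list at percentile 86.2, within the random range, and the planned matching on gene length at 97.8. Matching on exon junctions per kb put the immediate early list at 91.9, also within the random range.

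**Figure D2:**
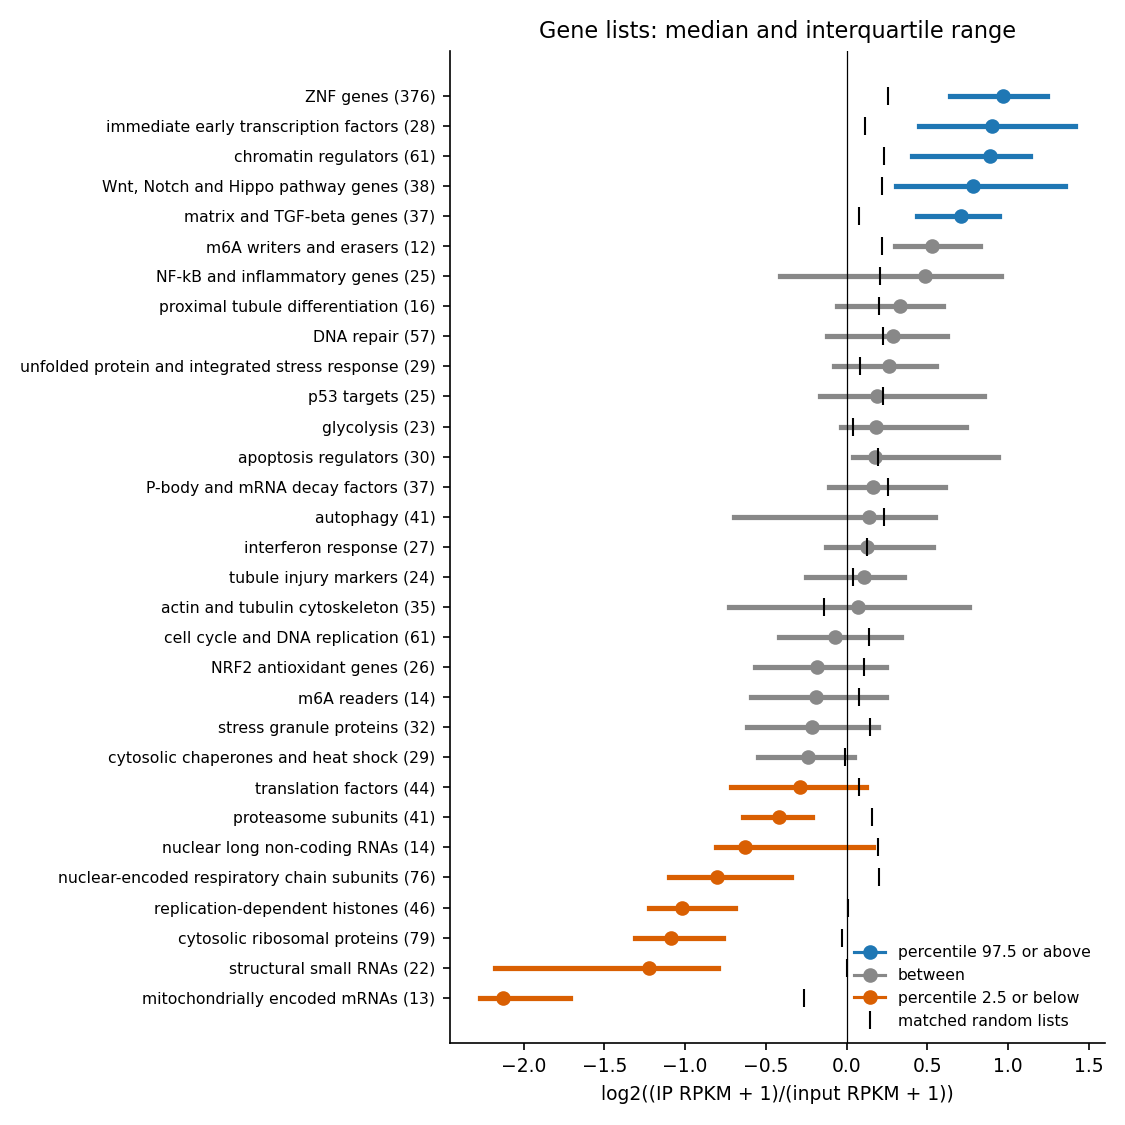
Median (point) and interquartile range (bar) of log2((IP RPKM + 1)/(input RPKM + 1)) over the measured members of each list, with their number in parentheses, and the median of expression-matched random lists (vertical tick), from 1 IP and 1 input library. The 5 lists above the random lists have medians from 0.71 to 0.97 and the 8 below from -2.13 to -0.29, on the deposited RPKM scale. With equal RPKM sums, the medians of 5 of the 8 (respiratory chain, histones, nuclear lncRNAs, proteasome and translation factors) turn positive.

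A further 8 lists lay below random lists. The 13 mitochondrially encoded mRNAs were all lower (median -2.13, percentile 0), from MT-ND4L at -1.11 to MT-ND1 at -2.95. Together they took 0.715% of IP reads and 3.15% of input reads, a ratio of 0.227 (0.226 to 0.229). Cytosolic ribosomal protein mRNAs had 46 of 79 members lower and 0 higher (median -1.09, percentile 0), with RPS12 (-1.89) and RPL12 (-1.71) lowest and RPL3 (0.26) highest. Nuclear-encoded respiratory chain subunits had 26 of 76 lower and 0 higher (median -0.80, percentile 0), with COX6C at -1.80 and NDUFA1 at -1.76, while the large flavoprotein subunit SDHA was at 0.50. Replication-dependent histones, whose mRNAs end in a stem-loop without a poly(A) tail, had 24 of 46 lower and 0 higher (median -1.02, percentile 0), with H2BC3 at -1.94.

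Proteasome subunits had 2 of 41 members lower (PSMA4 at -1.15 and PSMA3 at -1.02) and 0 higher (median -0.42, percentile 0.04). Matched also on coding transcript length the list was at 3.22, which ended the call, and in the planned matching on gene length at 0.07, which kept it. Translation factors had 4 of 44 lower and 0 higher (median -0.29, percentile 1.78). Within that list EIF3E (-1.22) and EIF1AX (-1.21) were lowest, and EIF4G1 (0.89) and EEF2 (0.84) highest. With equal RPKM sums, 7 of the 13 mitochondrial mRNAs were lower (median -1.02), and 0 of the 79 ribosomal protein mRNAs were lower and 4 higher (median -0.03), both lists still at percentile 0. On that scale the medians of the respiratory chain (0.11), histones (0.05), proteasome (0.64) and translation factors (0.82) turned positive, and the call for translation factors ended (percentile 4.04). A floor of 5 on the mean RPKM also ended it (percentile 5.17).

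Structural small RNAs had 11 of 22 members lower and 1 higher (median -1.22, percentile 0). The signal recognition particle RNA genes RN7SL1, RN7SL2 and RN7SL3 took 0.594% of IP reads and 6.72% of input reads, a ratio of 0.0883 (0.0877 to 0.0889). RN7SK, the RNA that holds P-TEFb inactive, took 0.208% and 1.29%, and RPPH1, the RNA of ribonuclease P, 0.0527% and 0.448%. SNORA73A, the higher member, rested on 22 IP and 8 input reads and lies within another listed gene over 100% of its bases. Nuclear long non-coding RNAs had 3 of 14 members lower and 2 higher (median -0.63, percentile 0.04). MALAT1, a nuclear speckle RNA, was at 168 RPKM in the IP and 715 in the input (-2.08) and GAS5 at -1.27, whereas TUG1 (1.58) and NORAD (1.01), which is known as a mainly cytoplasmic RNA despite its place in this list, were higher. At a mean RPKM floor of 5 this list was no longer below (percentile 20.8), and with equal RPKM sums its median was 0.34. Protein-coding genes as a whole took 93.1% of IP reads and 81.1% of input reads.

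The remaining lists lay within the random range. The medians of m6A writers and erasers, NF-kB, unfolded protein response, proximal tubule and DNA repair genes were positive on the deposited scale and under median centring, the trimmed mean and equal RPKM sums, and the signs of the other medians differed among these. For m6A writers and erasers 3 of 12 members were higher and 1 lower (percentile 84.8), with the adaptor genes RBM15 (1.89) and RBM15B (1.83) highest and METTL5 (-1.24) lowest. The m6A readers other than YTHDF1 had 2 of 14 higher (YTHDF3 and PRRC2A, at 1.05) and 2 lower (HNRNPA2B1 at -1.47 and HNRNPC at -1.07), at percentile 17.5. Genes for stress granule proteins had 3 of 32 higher and 0 lower (median -0.21, percentile 3.48), with USP10 (1.55) and LARP1 (1.26) highest and TIA1 (-0.93) lowest. Matched also on gene length, that list was at percentile 0.09, past the limit. P-body and decay factors had 4 of 37 higher and 0 lower (percentile 29.5), including TNRC6C (1.46).

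Among stress and injury lists, the unfolded protein and integrated stress response had 6 of 29 higher and 0 lower (percentile 82.3), with CEBPB at 1.56 and DDIT4 at 1.61 but ATF4 at -0.85. NRF2 antioxidant genes had 3 of 26 higher and 2 lower (percentile 7.96), with the NRF2 repressor KEAP1 at 1.42 and thioredoxin (TXN) at -1.80. NF-kB and inflammatory genes had 5 of 25 higher and 3 lower (percentile 91.7), with CSF1 at 2.03 and ICAM1 at 1.42, and CXCL8 at -1.52 and CXCL5 at -1.45. Tubule injury markers had 2 of 24 higher and 2 lower (percentile 62.7), with SOX4 (1.79) and HBEGF (1.03) opposite S100A6 (-1.28) and AREG (-1.27). The p53 targets had 4 of 25 higher and 0 lower (percentile 43.4, and 98.9 at a mean RPKM floor of 5), including BBC3 (6.47 RPKM in the IP and 1.65 in the input) and PHLDA3 (log2 ratio 1.37). Apoptosis regulators had 7 of 30 higher and 1 lower (percentile 46.8), with BOK at 2.02 and cytochrome c (CYCS) at -1.12. FADD (2.12) shared 59.2% of its exon bases with another listed gene. Chaperones had 0 of 29 higher and 2 lower (percentile 14), and interferon response genes 2 of 27 higher and 0 lower (percentile 49.5).

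Among housekeeping and tissue lists, cell cycle genes had 2 of 61 higher (MKI67 at 1.13 and E2F3 at 1.04) and 0 lower (percentile 7.14). DNA repair genes had 5 of 57 higher and 0 lower (percentile 68.0), and glycolysis genes 3 of 23 higher and 0 lower (percentile 74.0). Autophagy genes had 5 of 41 higher and 5 lower (percentile 29.3, and 0 at a mean RPKM floor of 5), from AMBRA1 at 1.40 to VMP1 at -1.90. Actin and tubulin genes also went both ways, with 7 of 35 higher and 5 lower (percentile 86.6). MYH10 (2.25) stood opposite TMSB4X (-1.24) and ARPC3 (-1.16). MYH9, chosen after its value was seen, was at 1010 RPKM in the IP and 239 in the input. Proximal tubule differentiation genes had 2 of 16 higher and 0 lower (percentile 69.6), with EHD1 at 1.12. Of 32 markers of blood, endothelium, fibroblast, smooth muscle and other nephron cells, 4 passed the floor, too few for a percentile: LUM (1.14), COL14A1 (0.13), CD68 (-0.24, with 85.6% of its bases shared) and CNN1 (-0.47).

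Most of the 5 highest non-coding genes had few reads, while AC106760.1 had 386 IP and 38 input reads, a ratio of 10.4 (7.41 to 14.9). RNA5SP202, a 5S rRNA pseudogene on chromosome 6 (4427963 to 4428081), had 54 IP reads and 0 input reads, at least 18.4-fold higher against a floor of 3 counts, while the exact interval of the read ratio starts at 14.4. AC106760.1 (log2 ratio 3.01), AC005943.2 (2.66) and AL162742.2 (2.63) lie with 100% of their bases in exons of ANKRD33B, MBD3 and ITPRIP or other listed genes, and the read ratios of these coding genes were 6.27, 3.27 and 4.21. MIR6819 (2.84), inside the MYH9 gene on the same strand, had 48 IP and 6 input reads, a ratio of 8.16 (3.49 to 23.3), beside 4.23 for MYH9.

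Of the 2220 genes higher by the size rule, 2212 were on the bound list of 4087 genes in the authors' deposited table. Both come from the same 2 libraries, and adding 1 RPKM to both values only shrinks a ratio. The overlap was thus largely fixed in advance and is no independent check. The deposited table also held 1686 genes with a log2 fold change of -1 or below and a p-value under 0.05. The p-values in the authors' deposited table were matched within 25% for 98.0% of 16048 genes by a negative binomial exact calculation with an assumed dispersion of 0.01, which also gave 4087 and 1686 genes past those limits. With an assumed dispersion of 0.16 the same calculation gave 998 and 324 genes.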

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

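No paired analysis was possible because each arm had 1 library, and leaving out a library was not possible for the same reason. Pseudocounts of 0.1 and 0.5, filters, protein-coding genes only and CPM kept the counts of higher and lower genes within 1.5 times. The numbers of lists above and below, 5 and 8, also stayed within 1.5 times wherever they were recomputed. Of the log2 ratios recomputed for named genes, 782 were the same within counting error and 422 moved. The 782 include values under changed filters, which cannot alter a gene's own ratio, so that count does not measure robustness. Among the ratios past the size rule, 4 changed sign, all under equal RPKM sums: DNAJA1 (0.0721), HNRNPC (0.0330), MT-ND4L (0.0013) and PSMA3 (0.0553). The cause was the shift of that scaling.

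Centring on the median gave 1290 higher and 1473 lower genes and a YTHDF1 log2 ratio of 1.0. The trimmed mean gave 1298, 1467 and 1.0. Equal RPKM sums gave 8311, 75 and 2.34, a shift of 1.11 on the log2 scale, to which RN7SL1 and RN7SL2 contributed with 34.6% of the input RPKM sum and 6.62% of that of the IP. Rescaling without mitochondrial and small non-coding RNA, chosen after seeing the data, gave 1499 and 1264 (54.3% higher). A limit of 10% shared exon bases, also chosen then, gave 1476 higher genes, as fewer genes were tested. A size rule of 1.5 gave 570 higher and 203 lower genes by construction. Depth limits genes with few reads, such as BEX2, while the absence of replicates limits every gene.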

Other observations

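The tests of input composition, of the DRACH motif as the whole cause and of the mitochondrial RNA share were chosen after the results were seen, as were the gene families, the gene architecture and the joint model described here. Among 116 families of genes with a common symbol stem and at least 10 measured members, several that no fixed list covered stood high in the IP. Semaphorins (SEMA) had 7 of 11 members higher and 0 lower (median log2 ratio 1.07), ZSCAN zinc finger genes 8 of 15 (1.02), unconventional and other myosins (MYO) 6 of 14 (0.90), G protein-coupled receptors named GPR 8 of 19 (0.80) and ZBTB transcription factors 15 of 38 (0.79), each with 0 lower. The PCDHGA protocadherins had 12 of 12 higher (1.11), but they share their last exons, so this is close to 1 measurement. Stems without a common function were high too, such as KIAA (9 of 23 higher, 0 lower, percentile 98.7) and LRRC (10 of 29, 0 lower, 99.2). A high percentile of a family therefore need not reflect its function. The HSPA stem had 3 of 14 higher and 0 lower (median 0.75, percentile 99.4), whereas the fixed chaperone list had 0 of 29 higher. On the low side were the LSM genes of RNA-binding rings (5 of 13 lower and 1 higher, -0.90), the SRSF splicing factors (3 of 12 lower, -0.84), mitochondrial ribosomal proteins (MRPL, 6 of 49 lower, -0.37, and MRPS, 3 of 29 lower, -0.44) and the ubiquitin-conjugating UBE family (7 of 38 lower and 2 higher, -0.33). With equal RPKM sums the medians of these low families turned positive, from 0.17 for LSM to 0.66 for MRPL.

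Gene architecture went with the ratio across genes, which are not independent replicates. Coding genes with transcripts under 1 kb had a median log2 ratio of -0.54 (747 genes) and those over 8 kb 0.66 (731 genes). Genes with 1 exon stood at 0.78 (264 genes), with 2 exons at 0.86 (505), with 5 to 8 exons at 0.05 (2993) and with 9 or more at 0.22 (5800). Where the longest internal exon exceeded 1000 bases, 301 of 706 genes were higher (median 0.90), against 240 of 1866 (median -0.15) where it had at most 150 bases. Among the 15 highest genes HPS6, FJX1 and SEPHS2 have 1 exon, and ZBED1, RTL6 and IRS1 have 2. SPEN has an internal exon of 8176 bases and THEMIS2 one of 1073. Others of the 15 went against this, with 43 exons in MYH10, 10 in FAM20C and 7 in RAB40C. The longest internal exon had only 134 bases in POGK, 141 in ANKRD33B and 145 in ARHGAP35. Of the histone genes, mostly of 1 exon, 24 of 46 were lower on the deposited scale and 0 with equal RPKM sums. GC content also went with the ratio (partial Spearman correlation 0.49 with transcript length and expression held fixed). A linear model on transcript length, GC content, junctions per kb, DRACH motifs per kb and expression took up 41.4% of the variance over 11077 genes. On its residuals the ZNF genes and immediate early factors were at percentile 100 (the latter at 91.9 when matched on junctions per kb and expression) and the Wnt, Notch and Hippo list at 99.0, while chromatin regulators (88.1), the matrix list (76.97) and proteasome subunits (22.7) lay within the random range. Genes for stress granule proteins (0.03) and autophagy (1.485), within the random range before, were below it, as were translation factors (1.56), with ribosomal proteins, respiratory chain, histones and mitochondrial mRNAs at 0.

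The relation of the ratio to exon junctions per kb (Spearman -0.30) was weighed against technical explanations. It stayed at -0.3768 with GC content and expression held fixed, where GC bias alone predicted a value between -0.1 and 0.1. With transcript length held fixed it was weaker, at -0.2159 (bootstrap interval -0.23 to -0.20), outside that range, so length could account for a part. DNA carried into the IP would add a constant amount, but the IP excess of genes with 1 or 2 exons was 4.293 times larger at a mean RPKM of 5 or more than at 1 to 5. This argues against DNA as the only source of that excess. A part from DNA stays open, since the mean includes the IP value and genes with more exons were not compared. The density of DRACH, the sequence context of m6A, had a correlation of -0.07 with the ratio. With GC content, transcript length and expression held fixed it was 0.1291 (bootstrap interval 0.11 to 0.15), above the 0.1 set beforehand for a contribution. The junctions were at -0.2857 with the same properties held fixed, and at -0.3289 with DRACH density held fixed too. Holding DRACH density fixed did not weaken the junction relation, so it is not the whole cause and was not shown to be a part. A candidate explanation, untested here without m6A maps, is that m6A is placed away from exon junctions and that YTHDF1 follows it. Binding of the antibody or beads to long RNA stays open without a control precipitation.

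The ribosomal protein mRNAs were weighed in the same way. Their median lay below all 10000 lists matched on transcript length (percentile 0.0) and on GC content (percentile 0.0), though length-matched lists themselves had a median of -0.47. The matching used 4 strata of expression and 10 of length or GC content. At that matching neither length nor GC content alone accounted for their place below other genes. An effect of length, GC content or expression differences within a stratum stays open. Their median was -1.311 relative to that of all genes, which a shift of all genes alike cannot change, so this value does not bear on the composition of the input. Whether they are lower in absolute terms stays open, since equal RPKM sums gave a median of -0.03 with 0 of 79 lower; reads shared with processed pseudogenes were not separated, and no biological explanation was tested.

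For the mitochondrial mRNAs, a lower share of all mitochondrial RNA in the IP would lower the mitochondrial rRNAs as well. The 2 rRNAs had a pooled read ratio of 1.16 with a lower bound of 1.132, and 21 mitochondrial tRNA genes had 0.562, both above the 0.227 of the mRNAs. Of these tRNA genes 12 were lower and 1 higher, with a median log2 ratio of -1.13 beside -2.13 for the mRNAs. The tRNA values argue against a loss of all mitochondrial RNA as large as that of the mRNAs. A smaller common loss stays open, since the tRNA genes were mostly lower too. The rRNAs took 0.0746% of IP reads and 0.0641% of input reads, against 3.15% of input reads for the 13 mRNAs. An rRNA removal that differed between the libraries could set the rRNA ratio. The rRNA ratio therefore cannot decide whether a common loss took place.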
